A study of Mus musculus with 2 samples.

How the data were processed

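The series holds ChIP-seq of H3K9ac, acetylation of histone H3 at lysine 9, in whole intestine of mouse embryos at embryonic day 14.5. Per the labels, the mice were of the strain given as B6NTac;B6NCrl/Lap, embryos of both sexes were pooled, replicate 1 was a pool of 24 embryos and replicate 2 a pool of 34 embryos, and the pools are biological replicates with 1 library each. Both libraries belong to 1 group, so the design holds no comparison between conditions. The fragment size range was 300 to 500 bp per the labels.

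The authors deposited 4 peak lists in narrowPeak form on the mouse build mm10, as the labels name it: a list for each replicate, a list called on both replicates pooled, and a list of replicated peaks. Per the labels' file notes, the lists were made from filtered alignments with control alignments. The aligner, the peak caller, their versions, the threshold and the rule that made a peak replicated are not given in the sources used here. The alignments, the control library and the signal tracks were not analysed here. Every deposited peak carries the authors' signal value, whose reference is not stated in the file notes, and a −log10 q value as the authors' peak caller gave it. Signal values were used only to describe, rank or filter peaks within a list. Peak lists hold no reads, so the depth of each library is unknown, no counting interval was computed, and a gene without a peak is one without a call at that unknown depth. The lists also hold weak peaks: a q above 0.05 was carried by 12.3% of the peaks of replicate 1, 12.9% of those of replicate 2, 10.1% of the pooled peaks and 1.21% of the replicated peaks.

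Gene positions came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, and sequence from the matching GRCm38.p6 genome. No peak in any of the 4 lists ended past the end of its chromosome. Peaks on sequences outside the assembled chromosomes, 8 in replicate 1, 6 in replicate 2, 5 in the pooled list and 4 in the replicated list, were left out of all comparisons. Coordinates are given from 1, on mm10. The annotation gave 21853 protein-coding genes with 54361 protein-coding transcript starts. Intervals were handled with bedtools 2.31.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

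A gene was called marked when a peak overlapped the 1 kb on either side of any of its protein-coding transcript starts. Its promoter domain was the widest stretch of peaks, merged over gaps of up to 1 kb, that overlapped this window, with a width of 0 where there was none. A domain can reach over neighbouring genes, which then share it. Genes were split into quintiles by the observed over expected CpG ratio in the 500 bp on either side of the most 5′ start. Peaks were assigned in order to protein-coding promoters, other promoters, exons, introns and intergenic sequence. A peak was distal when it lay over 1 kb from every annotated transcript start, and was then given to the gene with the nearest protein-coding start. The replicates' lists were compared by overlap of at least 1 bp, against 100 random placements of a list within its own chromosomes outside assembly gaps.

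Before the data were examined, 23 lists of gene symbols and 2 classes defined by symbol, olfactory receptors and ribosomal proteins, were fixed, together with the tests and the rule for named genes. Of 525 symbol entries, 524 matched a protein-coding gene, and Ahsp of the erythroid list did not. Each of the 25 lists was compared with all other protein-coding genes by a 2-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists at a threshold of 0.05. Because marking follows CpG content, the share of marked members was also ranked among 10000 random lists drawn from the same CpG quintiles. Median domain width was ranked in the same way. Unmarked genes entered with a width of 0, so a rank of width can partly repeat that of the share. Distal peaks per list were ranked among 10000 random lists matched on quintiles of the distance to neighbouring starts. Ranks above the 97.5th or below the 2.5th percentile were called higher or lower. The gut and the other-organ transcription factors were compared by a 2-sided Fisher's exact test and by a 2-sided permutation test of the median width with 100000 resamples. Genes are not replicates, and neighbouring or related genes are not independent, so these tests describe these libraries. The lists share members: 15 of the gut transcription factors are in the gut epithelium list, 5 in the gut mesenchyme list, 3 in the enteric neural crest list and 1 in the smooth muscle list, and 14 of the other-organ factors are in the central nervous system list. On simulated marking of lists of 24 genes drawn from the 21853, Fisher's exact test called 2% of unchanged lists and 35% of lists with 5 times the odds of marking, and the CpG-matched rank called 3% and 68.5%. The simulated lists were drawn at random, marked independently and judged on the unadjusted p. These rates are therefore not those of the adjusted test on lists of related genes.

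The genes named are the 25 with the widest promoter domain among genes marked in both replicates' own lists, the 3 members of each list with the widest domain, the unmarked members where under 4 were unmarked and otherwise the 3 first in the alphabet, the genes nearest the 10 strongest distal peaks, every unmarked Hox gene, and all members of lists of 10 or fewer. The text leaves out some genes that this rule names. Genes named outside it were chosen after their values were seen, and the text says so there. A peak in 1 replicate only, or alone, is one in that replicate's own list and not in the other's, whatever the pooled list held. Values per replicate come from each replicate's own list, and means with SD are over these n = 2 lists. The alternatives were each replicate's own list alone, the pooled list, replicated peaks that overlap both replicates' lists, a −log10 q of at least 5, the upper 50% of the list by signal value, promoter windows of 500 bp and 2.5 kb, the most 5′ start only, no merging or merging over 3 kb, distal distances of 2.5 kb and 10 kb, and overlaps of 50% of a peak or of both peaks.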

Results

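H3K9ac, a histone acetylation found at active promoters, was mapped in mouse intestine at embryonic day 14.5 in 2 pools of embryos. At this stage the gut tube holds epithelium, mesenchyme, developing smooth muscle, enteric neural crest, vessels and an outer mesothelium. The list of replicate 1 held 39549 peaks over 29622654 bp, that of replicate 2 held 29522 peaks over 22440630 bp, and the pooled list held 35110 peaks. The replicated list, used throughout unless stated, held 23884 peaks over 26243498 bp, or 0.963% of the genome, with a median width of 869 bp. It was a subset of the pooled list, of which it held 68.0%. Of its peaks, 20507 (85.9%) overlapped a peak in both replicates' own lists, 3165 overlapped a peak in 1 of them, and 212 overlapped neither.

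The first question was how far the pools shared their acetylated regions. Most regions of replicate 2 were found in replicate 1, where 24460 of its peaks (82.9%) overlapped a peak of replicate 1, against 2.28% for random placements. In the other direction 21710 peaks of replicate 1 (54.9%) were shared, against 1.69% for random placements. The replicates' lists had 62.2% of their joint base pairs in common. The strongest quartile of either list by its own signal value was shared at 100%, while the weakest quartile was shared at 13.0% in replicate 1 and 52.0% in replicate 2. Shared peaks lay at protein-coding promoters in 74.3% of cases in replicate 1 and 72.3% in replicate 2. Of the unshared peaks, 16.7% and 16.0% did so.

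**Figure D1:**
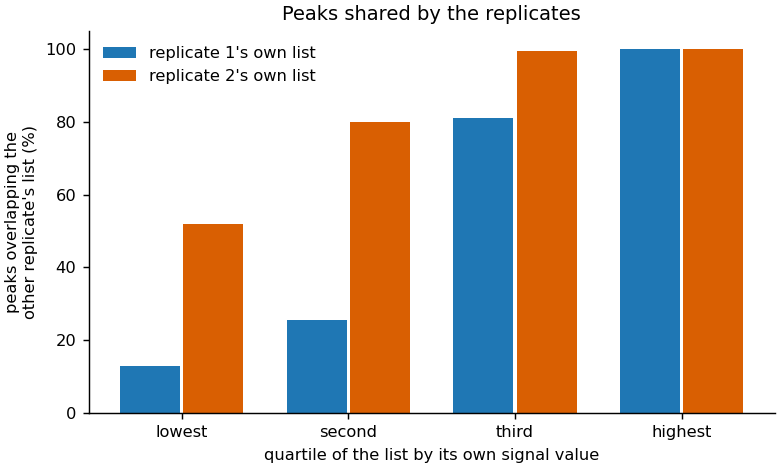
Share of each replicate's peaks that overlap the other replicate's list (y axis, %), by quartile of the list ranked by its own signal value (x axis), with a bar for each replicate. Sharing rises from 13.0% to 100% in replicate 1 and from 52.0% to 100% in replicate 2.

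Acetylation was concentrated at promoters. Protein-coding promoters held 16450 of the replicated peaks (68.9%) and 69.4% of their base pairs, against 2.44% of the genome, a 28.4-fold excess. Introns held 10.5% of the peaks and intergenic sequence 9.80%, with base pairs at 0.343-fold and 0.124-fold of their genomic shares. Promoter peaks were wider, with a median of 1150 bp against 404 bp for intronic peaks. A peak took the first class in order that it touched, so a wide peak was more readily assigned to a promoter. Part of the difference in width can come from this rule. The promoter share was 55.5% ± 10.2 (SD, n = 2) over the replicates' own lists, at 48.3% in replicate 1 and 62.7% in replicate 2.

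Of 21853 protein-coding genes, 13402 (61.3%) were marked. The replicates' own lists gave 62.2% ± 1.88 (SD, n = 2), and 13174 genes were marked in both, 717 in replicate 1 only and 136 in replicate 2 only. Marking followed promoter CpG content, from 7.34% of genes in the lowest quintile through 28.2%, 79.0% and 94.6% to 97.5% in the highest quintile. Over the replicates' lists the lowest quintile stood at 8.26% ± 1.23 (SD, n = 2) and the highest at 97.8% ± 0.404 (SD, n = 2), so the difference between quintiles far exceeded the spread between replicates. The median domain of a marked gene was 1422 bp in the lowest quintile and 2181 bp in the highest. The share in the lowest quintile fell to 4.14% with the upper 50% of peaks by signal value and to 2.81% with the most 5′ start only.

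**Figure D2:**
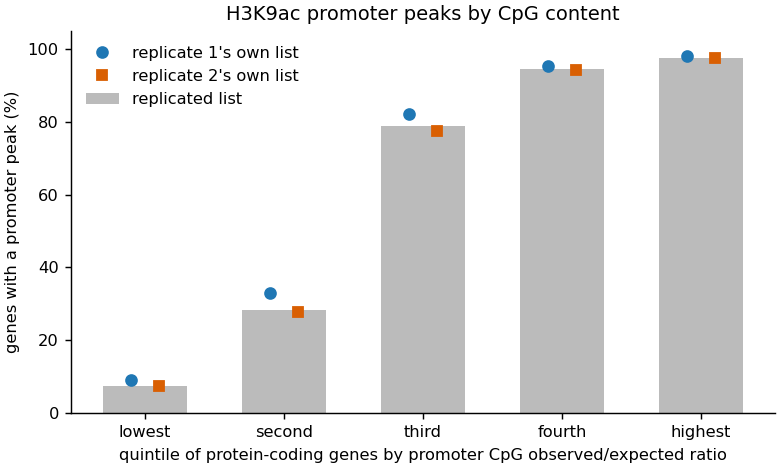
Share of protein-coding genes with a promoter peak (y axis, %) by quintile of the promoter CpG observed over expected ratio (x axis). Bars give the replicated list and points each replicate's own list, and the share rises from 7.34% to 97.5%.

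Genes of the cell types that build the gut wall carried the mark almost without exception in 3 lists. In the gut epithelium list 28 of 30 genes were marked, against 61.3% of all other genes (Fisher's exact test, adjusted p = 0.000192) and 63.1% in CpG-matched random lists. The widest epithelial domains lay at Gata4 (12658 bp, chromosome 14, 63239505 to 63252162), Gata6 (11138 bp, chromosome 18, 11048175 to 11059312) and Shh (8994 bp, chromosome 5, 28458104 to 28467097), coding for 2 endodermal transcription factors and the hedgehog ligand of the gut epithelium. Within the replicates' own lists Gata6 measured 11383 and 11062 bp, while Gata4 measured 11319 bp in replicate 1 and 4526 bp in replicate 2, and Shh 9905 and 5995 bp. Cdh17, coding for an intestinal cadherin, and Ehf were unmarked, Ehf with a peak in replicate 2 alone.

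In the gut mesenchyme list 28 of 29 genes were marked (Fisher's exact test, adjusted p = 4.39e-05), with a median domain of 4136 bp against 1185.5 bp in CpG-matched lists. Ptch1, the hedgehog receptor and target, had a domain of 22800 bp (chromosome 13, 63551236 to 63574035), the widest of any gene outside the Hox clusters and their overlapping gene models. Foxf1 (13038 bp) and Nkx2-3 (11730 bp), transcription factors of the splanchnic and gut mesoderm, followed. The exception was Barx1, a factor of the stomach mesenchyme, with a narrow peak of 272 bp in replicate 1 only. In the smooth muscle list 21 of 22 genes were marked (Fisher's exact test, adjusted p = 0.000851), led by the genes for tropomyosin 1, Tpm1 (8999 bp), filamin A, Flna (6633 bp), and enteric gamma-actin, Actg2 (5477 bp). Tpm1 and Flna measured 10138 and 7127 bp in replicate 1 but 4823 and 3407 bp in replicate 2. Kcnmb1, a potassium channel subunit of mature smooth muscle, was the unmarked member, with 553 bp in replicate 1 alone. In all 3 lists both the share and the median width lay above the 97.5th percentile of CpG-matched lists. Unmarked genes enter with a width of 0, so the rank of width partly repeats that of the share. With only the upper 50% of peaks by signal value, the epithelial share fell to 56.7% and no longer differed from other genes (Fisher's exact test, adjusted p = 0.470).

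For other cell types of the wall no difference from other genes was called in the replicated list. Lists this short leave the test little power, since without adjustment it called 35% of simulated lists of 24 genes with 5 times the odds. The enteric neural crest list had 17 of 24 genes marked (Fisher's exact test, adjusted p = 0.441), 19 in replicate 1 and 15 in replicate 2. Its widest domains were at Hand2 (11775 bp) and Tbx3 (7689 bp), which other gut cells also express, and at Phox2b (4044 bp), a factor of autonomic neurons, at 6516 and 2104 bp in the replicates' own lists. Dbh and Phox2a, genes of noradrenergic neurons, were unmarked in the replicated list, as was Fabp7, which had a peak in replicate 1. Of the endothelial genes 15 of 20 were marked (Fisher's exact test, adjusted p = 0.290), led by Egfl7 (6181 bp), Fli1 (3351 bp) and Ets1 (2773 bp), with Emcn, Lyve1 and Robo4 among the unmarked. The endothelial share lay at the 97.0th percentile of CpG-matched lists, with 17 genes marked in replicate 1 and 14 in replicate 2. Fli1 measured 5330 bp in replicate 1 and 2720 bp in replicate 2. With the upper 50% of peaks by signal value the endothelial share was 15.0%, below that of other genes (Fisher's exact test, adjusted p = 0.00379). Of the mesothelial genes 5 of 10 were marked (Fisher's exact test, adjusted p = 0.524): the transcription factor genes Bnc2 (3748 bp), Wt1 (2351 bp), Bnc1 (1067 bp) and Tbx18 (378 bp), and Aldh1a2 (2846 bp), which codes for a retinoic acid synthase. The unmarked were the surface protein genes Msln, Upk3b, Upk1b, Gpm6a and Lrrn4, of which Lrrn4 had 1798 bp in replicate 1 alone. Tbx18 measured 1109 bp in replicate 1 and 338 bp in replicate 2.

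Absorptive enterocyte genes, and the list of secretory and stem cell genes, were marked less often than other genes. Of the absorptive enterocyte genes 3 of 22 were marked (Fisher's exact test, adjusted p = 1.56e-05), against 34.5% in CpG-matched lists. They were Mttp (2454 bp), needed for lipoprotein assembly, and the brush-border peptidases Dpp4 (1197 bp) and Anpep (864 bp), the same number as in replicate 2 and fewer than the 5 of replicate 1. Dpp4 and Anpep measured 777 and 549 bp in replicate 2. Alpi, coding for intestinal alkaline phosphatase, and the apolipoprotein genes Apoa1 and Apoa4 were unmarked in both replicates. Of the secretory and stem cell genes 6 of 20 were marked (Fisher's exact test, adjusted p = 0.00732), led by Smoc2 (2950 bp), Insm1 (2285 bp) and Ascl2 (1874 bp). In replicate 2 Smoc2 measured 1777 bp and Insm1 measured 951 bp, against 2978 and 2865 bp in replicate 1. The marked members were the stem cell genes Smoc2, Ascl2 and Lgr5 (716 bp), the tuft cell genes Dclk1 and Pou2f3, and Insm1, an enteroendocrine factor gene. Of these, Lgr5, Dclk1 and Pou2f3 were named after their values were seen. Whole intestine was used, so these peaks do not show which cells carried the mark. Agr2 and Chga, of goblet and enteroendocrine cells, were unmarked, and Atoh1, the secretory lineage factor, had 396 bp in replicate 1 only. With replicate 1's own list, without replicate 2, 45.0% of this list were marked and the difference was not significant (Fisher's exact test, adjusted p = 0.123), as with the pooled list (Fisher's exact test, adjusted p = 0.123).

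Blood cell genes were marked less often than other genes, but at the level of their CpG content. Of the leukocyte genes 4 of 20 were marked (Fisher's exact test, adjusted p = 0.000425), the 26.5th percentile of CpG-matched lists, with 8 in replicate 1 and 5 in replicate 2. They included the haematopoietic factor genes Runx1 (1635 bp) and Ikzf1 (1109 bp) and the actin-binding Coro1a (712 bp), whereas the macrophage gene Adgre1 and the lymphocyte genes Cd19 and Cd3e were unmarked. Coro1a measured 1808 bp in replicate 1 and 332 bp in replicate 2. Of the erythroid genes 5 of 18 were marked in the replicated list and in each replicate (Fisher's exact test, adjusted p = 0.00779), the 76.9th percentile of matched lists. Tal1 (1822 bp), Klf1 (1343 bp) and Epor (913 bp) were among them, and Gata1, Alas2 and Epb42 were not.

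Genes of other organs were largely unmarked, including those of organs next to the intestine. In the pancreas list 1 of 20 genes was marked (Fisher's exact test, adjusted p = 7.54e-07), Mnx1 (868 bp), with 5 in replicate 1 and 3 in replicate 2. In the hepatocyte list 1 of 24 was marked (Fisher's exact test, adjusted p = 3.00e-08), Apoh (1969 bp), with 1 in replicate 1 and 2 in replicate 2. The Apoh domain (chromosome 11, 108342578 to 108344546) lay at the most 5′ start of a gene model reaching to 108414396. This start was in CpG quintile 4, whereas the other hepatocyte genes were in quintile 1 or 2. Whether the domain belongs to a neighbouring gene was not examined. Alb, Afp and Ahsg, which fetal liver expresses abundantly, had no promoter peak in either replicate. In the list of foregut, lung, thyroid and stomach 2 of 20 were marked (Fisher's exact test, adjusted p = 8.84e-06), the ciliogenesis factor gene Foxj1 (1762 bp) and Sox2 (699 bp), but not the gastric proton pump genes Atp4a and Atp4b. Foxj1 measured 3195 bp in replicate 1 and 1509 bp in replicate 2, and Sox2 326 and 1339 bp. Ryr2 (1147 bp) and Tnni3 (715 bp) were the 2 marked of 22 cardiac and skeletal muscle genes (Fisher's exact test, adjusted p = 1.82e-06), with 4 in replicate 1 and 1 in replicate 2, where Tnni3 had no peak. Dazl (798 bp) was the 1 marked of 20 germ line genes (Fisher's exact test, adjusted p = 7.54e-07). All 5 lists stood below the 2.5th percentile of CpG-matched lists. Among these 6 lists of other organs, that of the central nervous system lay furthest below its CpG-matched mean, with 6 of 28 genes marked against 88.4% in matched lists (Fisher's exact test, adjusted p = 4.34e-05). Its marked members included the homeobox genes Dlx1 (4095 bp), Dlx2 (3292 bp) and Dlx5 (435 bp), while Dlx6, Emx1 and Emx2 were unmarked. The Dlx1 domain measured 3978 bp in replicate 1 and 293 bp in replicate 2, and that of Dlx5 210 and 422 bp.

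**Figure D3:**
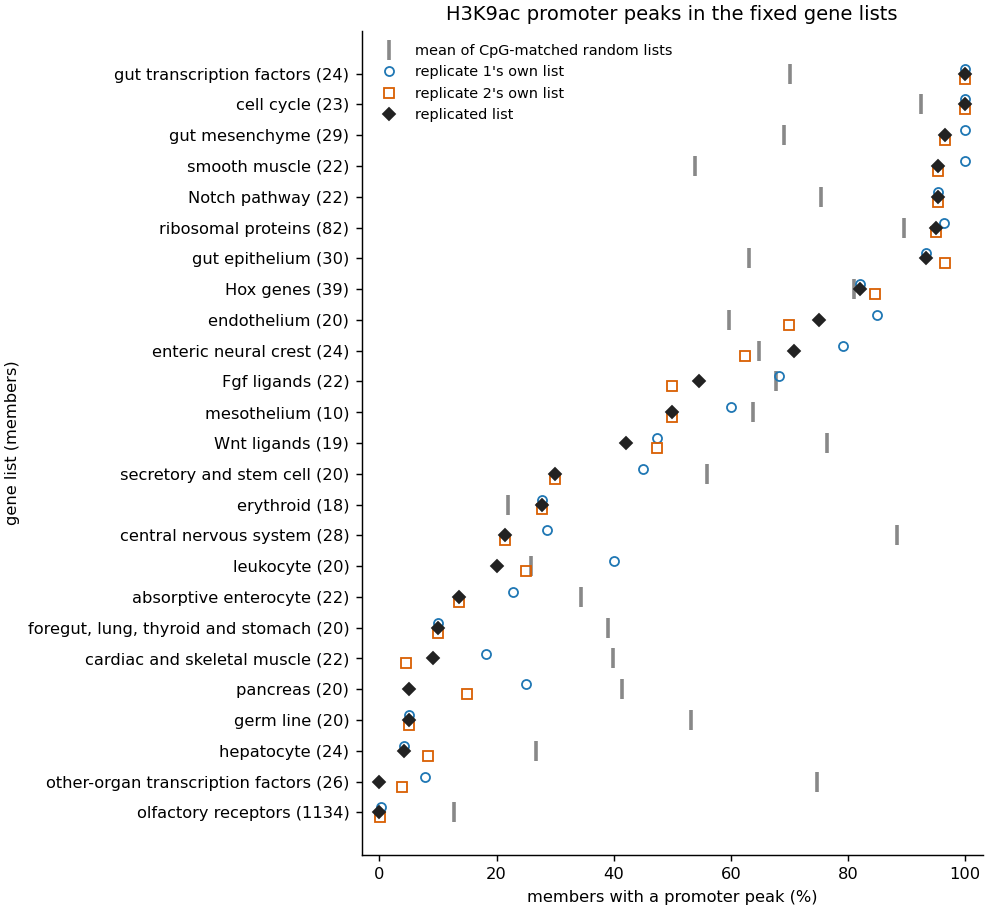
Share of members with a promoter peak (x axis, %) in each fixed gene list (y axis, number of members in parentheses). Diamonds give the replicated list, open symbols each replicate's own list and grey ticks the mean of 10000 CpG-matched random lists. The gut transcription factors stand at 100% and the other-organ transcription factors at 0%.

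The lists of gut and other-organ transcription factors, genes that often have CpG-rich promoters in any tissue, were compared directly. All 24 gut factors were marked in the replicated list and in each replicate, and 0 of 26 other-organ factors were marked in the replicated list (Fisher's exact test, p = 8.23e-15). The other-organ factors had 2 marked members in replicate 1, 1 in replicate 2 and 3 in the pooled list. The median domain was 4515.5 bp against 0 bp (permutation test, p = 2e-05, the smallest that 100000 resamples can give). Unmarked genes have a width of 0 by definition, so this test restates the difference in marking and is no separate evidence on width. Foxf1 (13038 bp), Gata4 (12658 bp) and Hand2 (11775 bp) had the widest domains among the gut factors in the replicated list. In replicate 2 Gata4 measured 4526 bp, less than Nkx2-3 (11704 bp) and Gata6 (11062 bp), among others. Emx1, a forebrain factor gene, had 245 bp in replicate 1 alone, and En1, a midbrain and hindbrain factor gene, had 368 bp in replicate 2 alone. Factor genes outside these lists did not all follow them, since Dlx1, Dlx2, Dlx5, Otx1, Pou3f2, Hes5, Sox2, Foxj1 and Mnx1, among others, of the other-organ cell type lists were marked and Barx1, Ehf, Phox2a, Atoh1, Neurog3, Neurod1, Spdef and Gfi1, among others, of the gut wall lists were not. These exceptions were partly chosen after their values were seen. The median CpG ratio was 0.571 for the gut factors and 0.627 for the other-organ factors. With the upper 50% of peaks by signal value 58.3% of the gut factors were marked against 0% (Fisher's exact test, p = 2.09e-06), and the median gut domain was 2324.5 bp there and 2544.5 bp without merging.

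**Figure D4:**
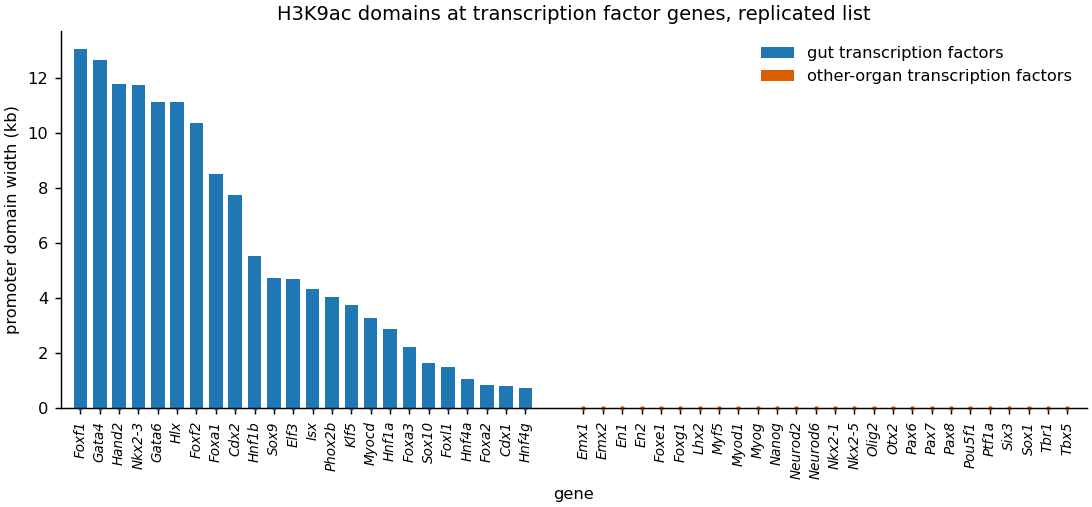
Width of the promoter domain in the replicated list (y axis, kb) for each gene of the gut and the other-organ transcription factor lists (x axis). All 24 gut factors have a domain, the widest at Foxf1 (13038 bp), and all 26 other-organ factors stand at 0.

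Genes of 3 developmental signalling families were examined next. The Notch pathway was marked at 21 of 22 genes in the replicated list and in each replicate (Fisher's exact test, adjusted p = 0.000851), with wide domains at the target gene Hes1 (8343 bp) and the ligand gene Jag1 (5265 bp) and with Notch4 unmarked in the replicated list and in replicate 1. The Notch share fell to 59.1% with the upper 50% of peaks by signal value and no longer differed from other genes (Fisher's exact test, adjusted p = 0.437). Of the Wnt ligands 8 of 19 were marked (Fisher's exact test, adjusted p = 0.119), below every one of the 10000 CpG-matched lists, whose mean was 76.5%. Wnt5a, a ligand of the gut mesenchyme, had a domain of 8617 bp, ahead of Wnt9a (2762 bp) and Wnt2b (1582 bp), and Wnt1, Wnt10a and Wnt10b were unmarked. Wnt9a measured 3009 bp in replicate 1 but 1328 bp in replicate 2, less than Wnt2b there (1566 bp). Of the Fgf ligands 12 of 22 were marked (Fisher's exact test, adjusted p = 0.524), with 15 in replicate 1 and 11 in replicate 2. Fgf9 (6726 bp), Fgf11 (5339 bp) and Fgf10 (3402 bp) had the widest domains, and Fgf1, Fgf14 and Fgf16 were unmarked in the replicated list. Of these, Fgf1 was marked in both replicates' own lists, with 375 bp in replicate 1 and 456 bp in replicate 2. Fgf14 had 431 bp in replicate 1 alone. With the upper 50% of peaks by signal value, 15.8% of Wnt ligands (Fisher's exact test, adjusted p = 0.00614) and 13.6% of Fgf ligands (Fisher's exact test, adjusted p = 0.00134) were marked, both lower than other genes.

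Genes of general cell functions were mostly marked. All 23 cell cycle genes were marked in the replicated list and in each replicate (Fisher's exact test, adjusted p = 3.51e-05), at the 91.9th percentile of CpG-matched lists, with Plk1 (3962 bp), Mcm5 (3633 bp) and Rrm2 (3393 bp) widest, Mcm5 at 1982 bp in replicate 2. Of 82 ribosomal protein genes 78 were marked (Fisher's exact test, adjusted p = 1.82e-11), with a median domain of 2400 bp. Of 1134 olfactory receptor genes 0 were marked in the replicated list, 2 in replicate 1 and 1 in replicate 2, against 12.7% in CpG-matched lists and 64.7% of other genes, the latter a difference whose Fisher's exact p was too small to be represented. Over the 25 lists, 8 were marked more often than other genes by Fisher's exact test, 12 less often and 5 had no called difference. With the upper 50% of peaks by signal value 4 lists were marked more often by this test. Ranked among CpG-matched lists, the share in the replicated list was higher in 6 lists and lower in 11. There the Hox and cell cycle shares were not higher and the leukocyte and erythroid shares not lower, while the Wnt share was lower.

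The Hox genes, which pattern the body axis in order along 4 clusters, were marked at 32 of 39 genes (Fisher's exact test, adjusted p = 0.00975), the 56.4th percentile of CpG-matched lists. The share fell to 61.5% with the upper 50% of peaks by signal value and no longer differed from other genes (Fisher's exact test, adjusted p = 0.172). Their domains were far wider than those of matched lists, with a median of 5851 bp against 1430 bp. Neighbouring Hox genes share domains, and the median itself is the width of a domain shared by Hoxb7 and Hoxb8. The widths are therefore not separate values, and the matched lists were drawn without regard to position. All 11 genes of cluster A were marked, 8 of 10 in cluster B, 6 of 9 in cluster C and 7 of 9 in cluster D. By paralogue group, 10 of 12 genes of groups 1 to 4 were marked, 11 of 11 of groups 5 to 8, 4 of 4 of group 9 and 7 of 12 of groups 10 to 13. The covered part of the promoter window had a median of 79.8% in groups 5 to 8 and 28.6% in groups 10 to 13, at 38.8% and 19.4% in the replicates' own lists for the latter. Hoxb13, Hoxc11, Hoxc12, Hoxc13 and Hoxd1 were unmarked in both replicates, and Hoxb1 and Hoxd12 had a peak in replicate 2 only. The median width depended on the merging of peaks, at 2543 bp without merging and 27941 bp with gaps of up to 3 kb.

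**Figure D5:**
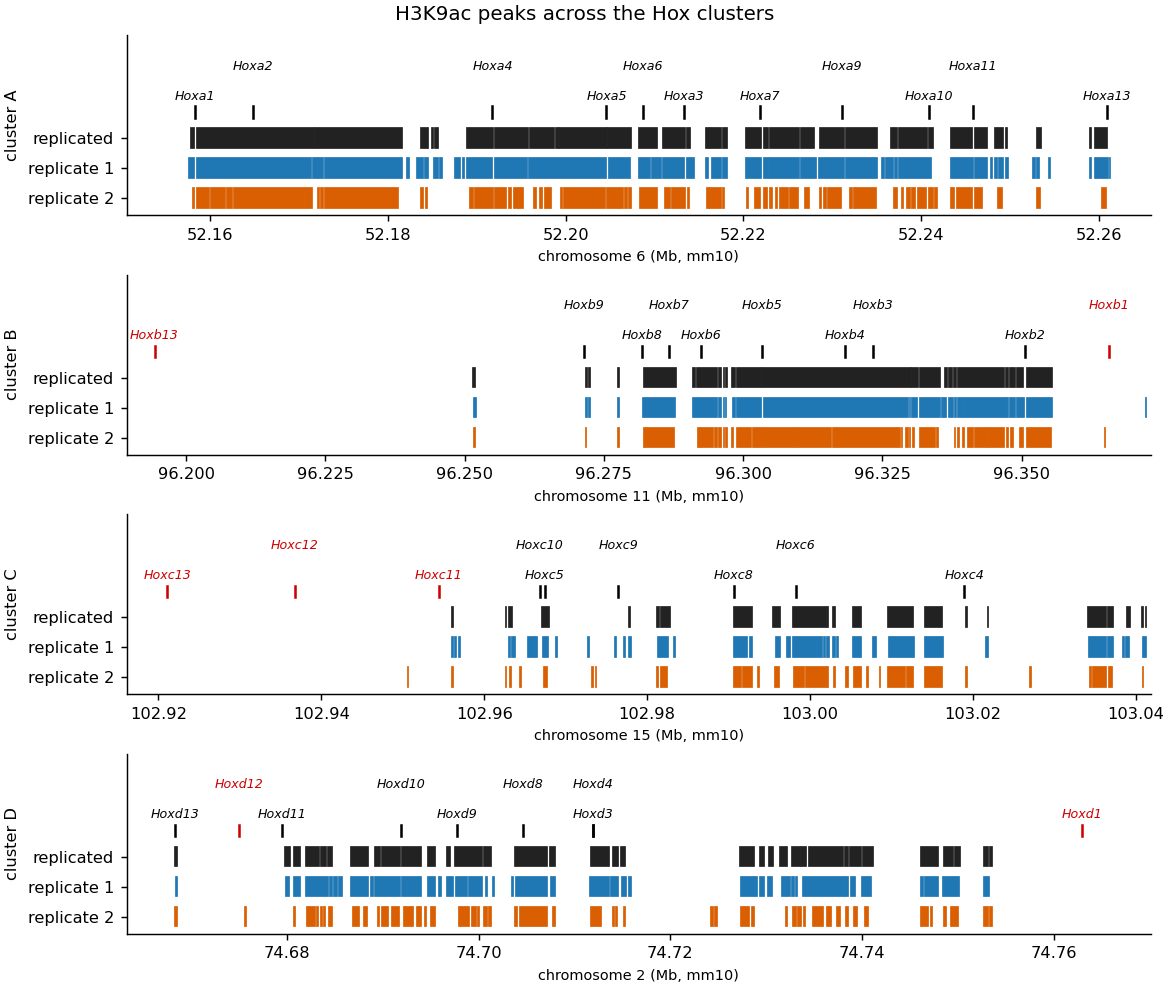
Peaks of the replicated list and of each replicate's own list across the 4 Hox clusters (x axis, position in Mb on mm10), with ticks at the 5′ end of each gene. Gene names in red have no promoter peak in the replicated list, which applies to 7 of the 39 genes.

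Of the 25 genes with the widest domains 15 were Hox genes, most of which shared a domain with a neighbour. The widest, 64521 bp on chromosome 11 from 96290882 to 96355402, was shared by Hoxb2, Hoxb3, Hoxb4, Hoxb5 and Hoxb6. It measured 57409 bp in replicate 1 and 43121 bp in replicate 2, where Hoxb2 lay in a separate domain of 5894 bp. On chromosome 6 the domains of Hoxa3 to Hoxa6 (25215 bp) and of Hoxa1 and Hoxa2 (23859 bp) came next. The first measured 17518 bp at Hoxa5 and 6018 bp at Hoxa4 in replicate 2. Outside the clusters and after Ptch1, the widest were those of the homeobox gene Meis2 (21218 bp, chromosome 2, 116055114 to 116076331), the nuclear receptor gene Nr2f2 (21191 bp, chromosome 7, 70349382 to 70370572), Mab21l2 (17345 bp), Bahcc1 (16567 bp), the T-box gene Tbx2 (15835 bp) and Meis1 (15823 bp). Lrba was given the domain of Mab21l2, which lies within it on chromosome 3. In the replicates' own lists Meis2 measured 21466 and 20351 bp and Nr2f2 measured 22669 and 19172 bp.

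Away from transcript starts, 5735 replicated peaks (24.0%) were distal, with a median width of 443 bp. The gut mesenchyme list had 65 distal peaks, 5.53 times the mean of territory-matched random lists, the gut epithelium list 39 (4.28 times) and the smooth muscle list 28 (3.96 times). The Notch pathway had 41 (6.12 times), of which 13 were nearest to Maml3 and 7 to Hes1, and the Hox genes had 41 (8.08 times). The gut transcription factors had 46 (5.25 times), the Wnt ligands 18 (3.01 times) and the cell cycle genes 16 (3.56 times), all above the 97.5th percentile in the replicated list at the 1 kb distance. Distal peaks were counted without merging, so parts of a wide promoter domain over 1 kb from a start counted as distal. The random lists were not matched on marking or domain width. These excesses can therefore partly repeat the wide promoter domains, as in the Hox clusters. The counts were larger in the longer lists of the replicates, at 132 in replicate 1 and 98 in replicate 2 for gut mesenchyme, 90 and 72 for gut epithelium, 55 and 37 for smooth muscle, 87 and 57 for Notch, 64 and 81 for Hox, 110 and 75 for gut transcription factors and 44 and 24 for Wnt ligands, each still above the 97.5th percentile. Olfactory receptors had 14, the lowest against matched lists at 0.0730 times. The other 16 lists did not stand apart, among them the other-organ transcription factors with 14 (1.37 times). Genes with the most distal peaks, chosen after their values were seen, were Cstad (16), Zfp36l1 (15), Bcor (14) and Maml3 (13). Of the 10 strongest distal peaks 7 lay between genes, the strongest on chromosome 7 from 73615781 to 73619507, nearest to Chd2 at 74035 bp, and all 10 were present in both replicates.

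The distal share was 43.9% in replicate 1, 29.9% in replicate 2, 38.4% in the pooled list and 4.77% in the upper 50% by signal value. The Wnt (13 peaks) and cell cycle (8) lists lost their calls at 2.5 kb, smooth muscle (9) at a −log10 q of at least 5, and gut epithelium (3) and smooth muscle (1) in the upper 50% by signal value. Over 10 kb from a start, 8.42% of peaks were distal, and the gut epithelium (10 peaks), smooth muscle (8), gut transcription factor (11), Hox (2) and cell cycle (1) lists no longer stood apart. Without replicate 1 the cell cycle list did not stand apart either (15 peaks), and without replicate 2 the enteric neural crest list did, with 51 peaks against 17 in the replicated list.

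The X chromosome carried 0.698 peaks per protein-coding gene against 1.12 on the autosomes, a ratio of 0.623. The ratio was 0.474 in replicate 1 and 0.561 in replicate 2. On the X, 42.7% of genes were marked, against 62.7% on the autosomes. Among the autosomes chromosome 14 was lowest at 0.835 peaks per gene and chromosome 12 highest at 1.34. The Y chromosome held 4 peaks.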

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

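Peaks lay on sequences outside the assembled chromosomes, which no comparison used: 4 in the replicated list. They were 2 on an unlocalised sequence of chromosome X, 1 on an unlocalised sequence of chromosome 4 and 1 on an unplaced sequence. The pooled list held 5 such peaks, replicate 1 held 8 and replicate 2 held 6.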

How the results depend on the processing

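Of 722 values under alternatives, 665 kept their direction and their side of the threshold or moved by less than the spread between replicates. Of all 722, 96 belong to results at 0 under every setting, such as median widths of 0 bp, and others had no call to lose, so the count of 665 overstates stability. For the overlap of the replicates' lists the spread was that between the 2 directions, 54.9% and 82.9%, and for the weakest quartile that between 13.0% and 52.0%. Spreads this wide let large moves pass, such as that of replicate 1's shared peaks from 54.9% to 71.0% with the upper 50% by signal value. For the weaker calls under a stricter threshold or a larger distance, fewer peaks entered by construction. The cause was not tested for the others. The depth of each library is unknown, so its effect on the calls could not be measured, and every alternative reuses the same libraries.

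Leaving out a replicate gave ranges of 48.3 to 62.7% for the promoter share, 60.9 to 63.6% for all genes marked, 7.39 to 9.13% for the lowest CpG quintile, 97.6 to 98.1% for the highest, 30.0 to 45.0% for secretory and stem cell genes, 29.9 to 43.9% for the distal share, 0.474 to 0.561 for the X ratio, 15 to 29 distal peaks for the cell cycle list and 22 to 51 for the enteric neural crest list. The pooled list gave 53.5% at promoters, 63.6% of genes marked, 98.2% in the highest quintile, 45.0% of secretory and stem cell genes, a distal share of 38.4% and an X ratio of 0.520.

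At a −log10 q of at least 5, 79.2% of replicate 1 was shared with replicate 2, 79.8% of peaks were at promoters, and 58.6% of genes, 6.09% of the lowest quintile, 96.4% of the highest and 31.6% of Wnt ligands were marked, the last then lower than other genes; smooth muscle had 9 distal peaks and lost its call. With overlap of 50% of both peaks, 56.9% of replicate 2 was shared. With the most 5′ start only, 58.5% of genes and 2.81% of the lowest quintile were marked, and with a window of 2.5 kb 8.97% of that quintile.

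The upper 50% by signal value put 91.6% of peaks at promoters and marked 49.7% of genes, 4.14% of the lowest quintile and 91.7% of the highest. In it 4 lists were higher, in place of 8: gut epithelium (56.7%), Notch (59.1%), Hox (61.5%) and gut transcription factors (58.3%) lost the call. Endothelium turned to lower (15.0%), and Wnt (15.8%) and Fgf (13.6%) became lower. Width calls were lost for cell cycle (1953 bp), Notch (1679.5 bp), and Wnt, Fgf and other-organ factors (each 0 bp), and distal calls for gut epithelium (3 peaks) and smooth muscle (1). The distal share was 4.77%. Without merging, width calls were lost for cell cycle (1823 bp) and Fgf (382.5 bp).

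At a distal distance of 10 kb the share was 8.42%, and the calls ended for gut epithelium (10 peaks), smooth muscle (8), Hox (2) and gut transcription factors (11), while cell cycle, at 1 peak, came out below its matched mean. At 2.5 kb the calls ended for cell cycle (8) and Wnt (13). The contrast of gut and other-organ transcription factors stayed past its threshold in all 17 values computed for it.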

Other observations

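Gene families sorted by symbol, a choice made after the data were seen, gave further differences between related genes. All 9 Pax genes were unmarked (Fisher's exact test, adjusted p = 0.000429 over 20 families), against 70.8% in CpG-matched lists, although 11.1% of them had a peak in replicate 1. Pax3, Pax4, Pax6, Pax7, Pax8 and Pax9 are also in the fixed other-organ lists, so the Pax result partly repeats theirs. Several Tbx and Fox genes are in the fixed lists too. Of 53 keratin genes 6 were marked (Fisher's exact test, adjusted p = 2.51e-13), among them Krt8 (1965 bp), Krt18 (923 bp) and Krt19 (1686 bp) of simple epithelia, which are also in the gut epithelium list, and Krt7 (1077 bp). The others marked were Krt10 (1624 bp), a keratin of stratified epidermis, and Krt222 (487 bp), while Krt20 of the intestinal epithelium was unmarked. Krt18 measured 1698 bp in replicate 1 and Krt7 255 bp in replicate 2. Protocadherins were marked at 14 of 69 genes (Fisher's exact test, adjusted p = 2.29e-11), against 72.2% in matched lists, with Pcdh7 (6638 bp) and Pcdh18 (4917 bp) widest. In contrast 16 of 17 Klf genes were marked (Fisher's exact test, adjusted p = 0.00840), Klf17 being the exception, against 82.4% in matched lists, at the 97.0th percentile, so the share did not stand apart from CpG content. Their median domain of 3719 bp lay above every CpG-matched list. All 7 Meis and Pbx genes, which code for partners of Hox proteins, were marked, with a median domain of 3098 bp at the 99.96th percentile, although their share did not pass the test (Fisher's exact test, adjusted p = 0.0804).

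Of 13 Tbx genes 5 were marked, Tbx2 (15835 bp) and Tbx3 (7689 bp) with wide domains and Tbx6 (1136 bp), Tbx1 (437 bp) and Tbx18 (378 bp) with narrow ones (Fisher's exact test, adjusted p = 0.224). Tbx1 measured 251 bp and Tbx18 1109 bp in replicate 1. Of 44 Fox genes 27 were marked against 82.4% in CpG-matched lists (Fisher's exact test, adjusted p = 1), with Foxf1 (13038 bp), Foxf2, Foxa1 and Foxp2 widest. Zinc finger genes named Zfp were marked at 337 of 394 (Fisher's exact test, adjusted p = 1.99e-25), against 71.8% in matched lists. Vomeronasal receptor genes were marked at 1 of 331 (Fisher's exact test, adjusted p = 5.18e-135).

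Among the tests that follow, those on the transcription factors and on the strength of unshared peaks were chosen after the results were seen, and the others before. The design has 1 group, so no biological explanation was tested against another tissue or stage.

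In the replicated list the 24 factors of the gut list were marked and the 26 of the other-organ list were not, a division that factor genes outside these lists did not all follow. CpG content would need the gut promoters to be richer in CpG, but their median ratio differed from that of the other-organ factors by -0.0564, and the shares lay beyond the CpG-matched lists on both sides. The ratio was taken at the most 5′ start, whereas a gene could be marked at another start, as Gata4 was. With the most 5′ start only, 22 of 24 gut factors and 0 of 26 other-organ factors were marked. A calling threshold that just missed weak peaks might fill in with the longer lists. At most 11.5% of the other-organ factors were marked in the replicates' own or pooled lists. However, the pooled list marked 63.6% of all genes against 61.3% in the replicated list, so longer lists fill in few genes of any kind. They also come from the same libraries, so this value cannot decide about a threshold. CpG content at the most 5′ start is argued against by these values, and a calling threshold stays open. Activity of these genes in the gut may explain the division between these lists, which is a hypothesis, since no expression or second tissue was analysed here.

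The list of replicate 1 was longer than that of replicate 2. Of its unshared peaks 89.6% lay in the lower 50% of its own list by signal value, but so did 99.2% of the unshared peaks of the shorter list of replicate 2, so this value decides nothing about weak peaks passing the call in replicate 1. For carry-over of other organs or blood, 147 such genes were unmarked in replicate 2, and 9.52% of them were marked in replicate 1. The share was 8.37% for other genes (Fisher's exact test, p = 0.551) and 12.0% on average for CpG-matched genes, with the observed share at the 16.7th percentile, inside the random spread. Depth, threshold, carry-over and other differences between the pools stay open.

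The X chromosome had fewer marked promoters, 42.7% against 52.5% in CpG-matched autosomal genes, a difference of -9.74 points. The lowest of 10000 matched draws was 47.8%. The replicates' own lists gave 44.8% against 55.5% and 42.0% against 51.9%, so CpG content at the most 5′ start is argued against as the whole cause. Unnamed gene models are argued against as well, since without genes named only Gm or Rik the difference was -8.72 points. Marked X promoters had a median signal value of 8.04, 71.9% of that of matched autosomal promoters, whose draws began at 9.65. This is consistent with a lower dose of active X, as with 1 active X per cell, but reads lost to repeated X sequence could lower the signal too and were not tested.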
